A study of Mus musculus with 95 samples.

How the data were processed

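The values used are the log2 expression values deposited by the authors, which per the labels were made with RMA (robust multi-array average), and no raw image data were used here. The version of RMA and the probe annotation were not given in the sources used here. The table held 17306 probe sets, of which 16464 carried 1 gene symbol and were tested, 0 carried several, and 842 carried none and are not used here. Each gene had 1 probe set, so no choice between probe sets of a gene arose. All 16464 genes matched the RefSeq table by Entrez Gene ID with 0 symbols changed, and names only were taken from it, since the genome build of the probe annotation was not given in the sources used here. No coordinates are given for that reason.

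Per the labels, the animals were male C57BL/6 mice of 21 to 27 g, and the central part of the left lateral lobe of the liver was kept in RNAlater. RNA was extracted with RNeasy Mini columns and labelled with biotin by a 3' IVT Express kit. The values ran from 1.68 to 13.9 with 0 missing, the array 75th percentiles from 5.33 to 5.45, and the correlations between arrays from 0.977 to 0.996. No 2 arrays were identical. The labels do not say that each array is from a separate animal, so p-values measure only the spread between these samples.

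The tests used limma 3.58.1 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A linear model with a mean for each of 21 groups was fitted to all 95 arrays (residual degrees of freedom 74), and moderated t tests were made in 30 comparisons. These were 15 treated groups against the vehicle of their day, 3 dose trends on day 11, 6 differences of the high-dose effect between days 4 or 11 and day 1, 3 differences between compounds at the high dose on day 11, and 3 differences between vehicles. The dose trend was the slope of the group means of day 11 on the dose rank, from vehicle to high. The p-values of each comparison were adjusted over all 16464 genes by the method of Benjamini and Hochberg, and a gene is called at an adjusted p under 0.05. Where a group mean lies below the array median the gene is close to background there, and the log2 fold change is a lower bound of its size. Group values are given as mean ± SD and log2 fold changes ± SE from the model.

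The 38 gene lists were fixed by name before the data were examined, and tested in 18 comparisons with camera of limma, with a preset correlation between genes of 0.01. Each call was repeated with a correlation estimated for each list. Called members of a list are counted over all genes and adjusted over the list alone. The p-values of the lists were adjusted over the 38 lists of a comparison. The lists of metabolism were cholesterol synthesis, fatty acid and triglyceride synthesis, mitochondrial fatty acid oxidation and ketogenesis, peroxisomal and microsomal fatty acid oxidation (PPARA targets), lipid droplets and fatty acid uptake, lipoprotein assembly and secretion, bile acid synthesis and transport, oxidative phosphorylation, mitochondrial ribosome and translation, gluconeogenesis and insulin response, coenzyme A and carnitine metabolism, and urea cycle and amino acid catabolism. Those of responses were CAR and PXR, NRF2, AHR, ATF4, endoplasmic reticulum chaperones, mitochondrial chaperones and proteases, lysosome and phospholipid storage, glucocorticoid response, circadian clock, acute phase, interferon, cell cycle and p53. Those of cell types and sexes were male-biased and female-biased liver genes, pericentral and periportal hepatocytes, Kupffer cells and macrophages, stellate cells and fibroblasts, endothelial cells, cholangiocytes and gallbladder, lymphocytes and NK cells, neutrophils, erythrocytes, exocrine pancreas and adipose tissue.

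The groups, comparisons, lists, thresholds, alternatives and the rule for naming genes were chosen before the data were examined. By that rule, at the high dose on day 11 the 10 largest positive and 10 largest negative log2 fold changes were taken among called genes for which every treated array lay on the same side of every vehicle array. In every other comparison 3 each way were taken by the same rule, and for trends and differences among the called genes. For each list called at the high dose on day 11 the 3 called members with the largest change in the direction of the list were taken, and 2 in other comparisons. Cyp2b10, Cyp3a11, Cyp4a14, Cpt1a, Fasn, Sqle, Cyp7a1, Plin2, Cidec, Fgf21, Mttp and Gpnmb were followed whatever their values. Predicted genes and clone names were passed over, and of the genes taken those whose call depended on an array or setting are left out of the text in most places. For a further reason 1 more is not reported here.

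The alternatives were array quality weights, a fit of only the arrays compared, leaving out genes with a mean below the median of 3.10 (8232 kept), quantile normalizing the values again, centring each array on its median, blocks of 24 sample numbers as a factor, a variance trend with robust estimation, the estimated correlation for lists, and leaving out each array of the compared groups in turn. A linear term in the sample number was added after the data were seen. As a check of the code, 200 genes of known change were added to simulated values, and at a log2 change of 1 the fit recovered 99% of them in the amiodarone comparison of day 11 and 98% in the tetracycline comparison of day 1, with 9 and 11 unchanged genes called. Neither alternative scaling moved the median log2 fold change of all genes by more than 0.021 in any comparison.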

Results

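Gene expression was measured on 95 Affymetrix arrays of liver from male C57BL/6 mice, 10 weeks old, that were dosed by oral gavage with amiodarone, valproic acid, tetracycline or a vehicle. Amiodarone is an antiarrhythmic drug, valproic acid an antiepileptic drug and tetracycline an antibiotic, and the series title names drug-induced steatosis, the storage of fat in liver cells, as its subject. The high dose was sampled on days 1 and 4 with 4 arrays per group, and the low, mid and high doses were sampled on day 11 with 5 arrays per group. The doses were 6.7, 20 and 60 mg/kg of amiodarone, 125, 250 and 500 mg/kg of valproic acid, and 14.8, 44 and 133 mg/kg of tetracycline. Phosphate-buffered saline (PBS) was the vehicle for amiodarone and valproic acid, and water with ascorbic acid was the vehicle for tetracycline, each with 4 arrays on days 1 and 4 and 5 arrays on day 11. Array medians lay between 3.06 and 3.13 on the log2 scale, and the number of arrays limits the precision. Changes below are log2 fold changes ± SE against the vehicle of the same day, and genes are named by symbol.

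The 15 comparisons of a treated group with its vehicle ask which liver genes each compound changed at each dose and time. Valproic acid on day 1 changed the most genes, 2589 of the 16464 tested, and amiodarone and valproic acid at the high dose on day 11 changed 1161 and 1487. Tetracycline at the high dose changed 107 genes on day 1, and limma called 0 genes for it on days 4 and 11, where 1386 and 888 genes had an unadjusted p under 0.05. Chance alone would give 823 such genes.

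**Figure D1:**
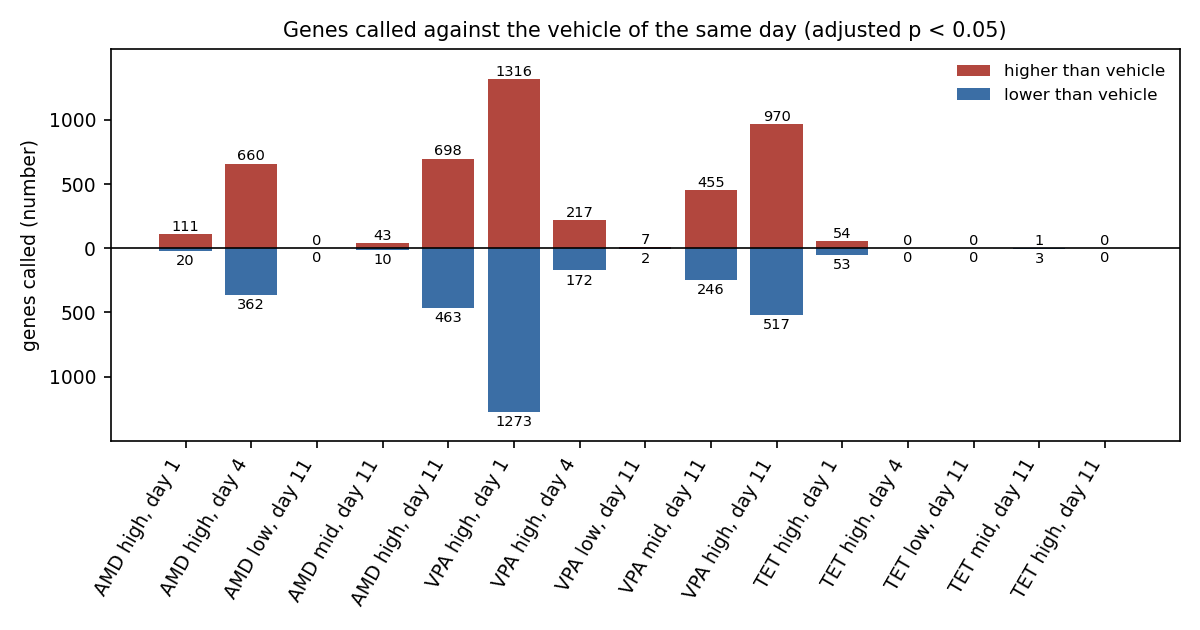
Number of genes called higher (above the line) or lower (below the line) than the vehicle of the same day at an adjusted p under 0.05, for each of the 15 treated groups (4 arrays per group on days 1 and 4, 5 on day 11). The tallest bars are those of valproic acid on day 1, with 1316 genes higher and 1273 lower.

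After 11 days of high-dose amiodarone, genes of fatty acid oxidation and of fat storage rose together. Cyp4a14 (Entrez Gene 13119), which encodes a microsomal fatty acid hydroxylase, stood at 12.63 ± 0.09 (SD, n = 5) against 7.41 ± 0.90 (SD, n = 5) with PBS, a 37.1-fold rise (5.21 ± 0.75, adjusted p = 1.5e-07). Its relative Cyp4a31 rose 29.3-fold (4.88 ± 0.29, adjusted p = 1.7e-24). Mogat1 (Entrez Gene 68393), which encodes a monoacylglycerol acyltransferase, rose by 2.68 ± 0.14 (adjusted p = 1.5e-26) from a vehicle level of 2.74 that lies below the array median, so this is a lower bound, and Cd36, which encodes a fatty acid transporter, rose 6.31-fold (2.66 ± 0.22). Every treated array lay above every vehicle array for these genes. Among the largest falls, Serpina12, which encodes the adipokine vaspin, fell to 0.192 of its vehicle level (-2.38 ± 0.39, adjusted p = 4.1e-06), and Slc22a7, which encodes an organic anion transporter, fell by 2.30 ± 0.35 on the log2 scale.

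Of 23 measured genes of peroxisomal and microsomal fatty acid oxidation, known targets of the receptor PPARA, 20 rose, or 21 adjusted over the list alone, with a median of 1.49 (list adjusted p = 8.7e-67). They included Acot1 (3.78 ± 0.31), Acot3 (3.46 ± 0.59), the pantetheinase gene Vnn1 (3.18 ± 0.28), Cyp4a10 (2.89 ± 0.33) and the peroxisomal enzyme gene Ehhadh (Entrez Gene 74147, 2.84 ± 0.16). Of 18 genes of mitochondrial fatty acid oxidation, 14 rose, or 15 adjusted over the list alone (median 0.59, list adjusted p = 2.4e-38), among them Eci1 and Decr1, both 1.14 ± 0.10, and the acylcarnitine carrier gene Slc25a20 (0.83 ± 0.09). Of 23 genes of lipid droplets and fatty acid uptake, 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (median 0.29, list adjusted p = 4.1e-16). Besides Mogat1 and Cd36 these were led by the lipoprotein lipase gene Lpl (1.45 ± 0.20). Plin2 (Entrez Gene 11520), which encodes a coat protein of lipid droplets, rose 1.84-fold (0.88 ± 0.13, adjusted p = 5.5e-07).

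Genes of drug metabolism and antioxidant defence rose as well. Of 23 genes of the response to the xenobiotic receptors CAR and PXR, 12 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.40, list adjusted p = 9.3e-13). Cyp2b10 (Entrez Gene 13088), a standard CAR target, rose by at least 2.23 ± 0.33 (adjusted p = 4.3e-07) from a vehicle level of 2.76, below the array median, Gstm3 rose by 1.30 ± 0.28 and Cyp2c55 by 1.29 ± 0.22. Of 21 NRF2 antioxidant genes, 11 rose and 1 fell, or 14 and 1 adjusted over the list alone (median 0.30, list adjusted p = 8e-12), with Gstm4 (1.23 ± 0.13), Nqo1 (1.01 ± 0.23) and Srxn1 (0.88 ± 0.11). Of 12 genes of mitochondrial chaperones and proteases, 4 rose, or 7 adjusted over the list alone (median 0.17), with Clpx (0.72 ± 0.17). Of 18 genes of coenzyme A and carnitine metabolism, 6 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.20, or 0.11 with dim genes left out), with the carnitine transporter gene Slc22a5 (0.84 ± 0.14). Of 21 genes of the mitochondrial ribosome, 4 rose, or 5 adjusted over the list alone (median 0.15), with Mrps9 (0.35 ± 0.08).

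Genes that fell under amiodarone included those of protein folding in the endoplasmic reticulum. Of 19 such chaperone and unfolded protein response genes, 10 fell, or 15 adjusted over the list alone (median -0.43, list adjusted p = 4.6e-13), with Sdf2l1 (-1.08 ± 0.28), Dnajb11 (-0.66 ± 0.16) and Xbp1 (-0.61 ± 0.12). Of 10 markers of periportal hepatocytes 3 fell, or 6 adjusted over the list alone (median -0.27), with Etnppl (-0.87 ± 0.18). Of 14 endothelial markers 3 fell, or 7 adjusted over the list alone (median -0.22), with Clec4g (-0.40 ± 0.07). Other single genes that fell were Enho, which encodes the peptide adropin (-1.75 ± 0.23), Adgrf1 (-1.61 ± 0.31), Sdr9c7 (-1.47 ± 0.21), the apolipoprotein gene Apoa4 (-1.38 ± 0.25), the oxysterol hydroxylase gene Cyp39a1 (-1.31 ± 0.19), Cyp2u1 (-1.30 ± 0.20) and Serpina9 (-1.27 ± 0.29).

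In this comparison 698 genes were called higher and 463 lower, 84 of them by more than 2-fold, and limma camera called 23 of the 38 lists with its preset correlation. The 11 lists above also passed with an estimated correlation, and the other 12 did not. Cholesterol synthesis (16 measured, 3 rose, or 7 adjusted over the list alone, median 0.46) had adjusted p = 0.25 with an estimated correlation. Nuclear genes of oxidative phosphorylation (23 measured, 5 rose, or 10 adjusted over the list alone) had adjusted p = 0.085 with an estimated correlation. Acute phase genes (20 measured, 6 fell, or 7 adjusted over the list alone, median -0.25) had adjusted p = 0.25 with an estimated correlation. Lipoprotein assembly (17 measured, 1 rose and 6 fell, or 3 and 7 adjusted over the list alone, median -0.13) had adjusted p = 0.076 with an estimated correlation, and its call was also lost when the values were quantile normalized again (adjusted p = 0.0783). Neutrophil markers (9 measured, 0 called, 1 adjusted over the list alone, median 0.31) had adjusted p = 0.28 with an estimated correlation, and without amiodarone array 012 their median was -0.08. Interferon response genes (18 measured, 0 called, 0 adjusted over the list alone, median 0.26) had adjusted p = 0.3 with an estimated correlation, and a median of 0.03 without array 062. The other 6 lists had adjusted p from 0.12 to 0.4 with an estimated correlation. The 27 lysosome and phospholipid storage genes, of interest because amiodarone accumulates in lysosomes, were not called as a list (2 rose and 6 fell, 2 and 7 adjusted over the list alone, adjusted p = 0.08), and Gpnmb was not called, with means of 3.00 and 2.80 below the array median.

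On day 4 high-dose amiodarone had changed 1022 genes, 660 higher and 362 lower, or 547 and 452 after quantile normalizing again. The same lipid lists rose, and cell cycle genes rose with them. Cyp4a14 rose by 5.02 ± 0.83 (adjusted p = 8.1e-06) and Cyp4a31 by 4.79 ± 0.32. Of 23 PPARA target genes 19 rose, or 20 adjusted over the list alone (median 1.36), and of 18 mitochondrial oxidation genes 15 rose, or 16 adjusted over the list alone (median 0.55). Of 23 lipid droplet genes 11 rose, or 15 adjusted over the list alone (median 0.35), with Mogat1 (2.41 ± 0.16), Cd36 (2.23 ± 0.25) and Plin2 (0.84 ± 0.15, adjusted p = 2.6e-05). Of 22 cell cycle genes 13 rose, or 16 adjusted over the list alone (median 0.54, list adjusted p = 4.8e-17), with Mcm6, part of the replicative helicase (1.47 ± 0.22, adjusted p = 4.5e-07). Of 16 p53 targets 3 rose, or 6 adjusted over the list alone, with the cell cycle inhibitor gene Cdkn1a (0.55 ± 0.09). The p53 list had a median of 0.21, and 0.12 without amiodarone array 053.

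NRF2 genes rose on day 4 (12 of 21, also 12 adjusted over the list alone, median 0.47), with Nqo1 (1.25 ± 0.26). CAR and PXR genes rose (10 of 23 higher and 2 lower, or 12 and 3 adjusted over the list alone, median 0.30), with Cyp2c55 (2.10 ± 0.24) and Cyp2b10 (1.71 ± 0.37). Mitochondrial chaperones (6 of 12, or 8 adjusted over the list alone, median 0.24) and the mitochondrial ribosome (5 of 21, or 14 adjusted over the list alone, median 0.20) rose, with Clpx (0.93 ± 0.18) and Tsfm (0.48 ± 0.11). Circadian clock genes fell (4 of 18, or 1 higher and 9 lower adjusted over the list alone, median -0.33), with the clock output gene Hlf (-0.62 ± 0.15). Pericentral markers (5 of 15, or 6 adjusted over the list alone, median -0.32, or -0.20 with blocks of sample numbers) fell, with Cyp2c37 (-0.69 ± 0.13). Periportal markers (3 of 10, also 3 adjusted over the list alone, median -0.22) fell, with Etnppl (-1.04 ± 0.20), and their median was -0.14 without amiodarone array 069 and -0.12 without PBS array 087.

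Of the 23 lists called on day 4, 13 also passed with an estimated correlation, the 12 named in the account of that day and coenzyme A and carnitine metabolism. The last (5 of 18 genes rose, median 0.08) was not called with dim genes left out (adjusted p = 0.0881), and its median was 0.05 without amiodarone array 053, 0.04 without PBS array 040 and 0.03 after quantile normalizing again. Cholesterol synthesis (10 of 16 higher, or 12 adjusted over the list alone, median 0.68) had adjusted p = 0.061 with an estimated correlation. Fatty acid and triglyceride synthesis (6 of 22 higher and 2 lower, or 10 and 2 adjusted over the list alone), in which Me1 rose by 1.78 ± 0.22 and Fads2 by 1.17 ± 0.13, had adjusted p = 0.089 with an estimated correlation. The other 8 lists had adjusted p from 0.068 to 0.42 with an estimated correlation. Single genes that fell on day 4 included Serpina12 (-2.33 ± 0.44), Slc22a7 (-2.31 ± 0.39) and Apoa4 (-1.71 ± 0.28).

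On day 1 high-dose amiodarone had changed 131 genes, 111 higher and 20 lower, and the fatty acid oxidation and CAR and PXR genes had already risen. Cyp4a14 rose 19.4-fold (4.28 ± 0.83, adjusted p = 0.00086), Cyp4a31 8.01-fold (3.00 ± 0.32) and Cyp2b10 by 1.86 ± 0.37 on the log2 scale (adjusted p = 0.0013). Of 23 PPARA target genes 15 rose, or 17 adjusted over the list alone (median 0.64). Of 18 mitochondrial oxidation genes 12 rose, or 14 adjusted over the list alone (median 0.36), with Eci1 (0.88 ± 0.11). Of 23 CAR and PXR genes 7 rose, or 15 adjusted over the list alone (median 0.40), and of 18 coenzyme A and carnitine genes 2 rose, or 5 adjusted over the list alone (median 0.16). Of 15 markers of stellate cells and fibroblasts 2 fell, also 2 adjusted over the list alone (median -0.17). Cyp2c70, an enzyme of bile acid metabolism in mice, fell by 0.58 ± 0.12.

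These 5 lists were those that passed with both correlations on day 1, of 16 called with the preset one. Endoplasmic reticulum chaperones (0 of 19 called, or 6 lower adjusted over the list alone, median -0.30) had adjusted p = 0.073 with an estimated correlation, and a median of -0.12 without PBS array 050. Kupffer cell and macrophage markers (0 of 16 called, median -0.43) had adjusted p = 0.17 with an estimated correlation, and a median of -0.23 without PBS array 025. The number of genes was 86 without amiodarone array 001, 80 without array 064 and 82 without PBS array 025, and it was 32 with only the arrays compared in the fit. The number of lists was 10 without array 013.

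Amiodarone at 20 mg/kg on day 11 changed 53 genes, 43 higher and 10 lower, and 2 lists were called higher with both correlations although few of their members were. Of 22 genes of fatty acid and triglyceride synthesis 1 rose, or 11 adjusted over the list alone (median 0.56, list adjusted p = 6.3e-11, adjusted p = 0.042 with an estimated correlation), and the gene was the malic enzyme gene Me1 (0.78 ± 0.19, adjusted p = 0.043). Of 14 genes of gluconeogenesis and insulin response 2 rose, or 5 adjusted over the list alone (median 0.25, adjusted p = 0.042 with an estimated correlation), Slc2a2, which encodes the glucose transporter of hepatocytes (0.38 ± 0.09), and Foxo1 (0.37 ± 0.08). The medians of these lists, the 2 of 15 called that passed with both correlations, were 0.36 without amiodarone array 083 and 0.12 without PBS array 020. Lynx1 fell by 0.44 ± 0.08 (adjusted p = 0.015). These gene calls rested on single arrays, since limma called 0 genes without PBS array 002 and 0 with only the arrays compared in the fit. The count was 1 without amiodarone array 066, 2 without 083, 22 without 091 and 140 without 065, and 4, 14 and 117 without PBS arrays 020, 032 and 073. Quantile normalizing again gave 55 genes, 39 higher and 16 lower.

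Amiodarone at 6.7 mg/kg gave 0 called genes in limma, with 776 at an unadjusted p under 0.05, and 1 gene without PBS array 002. The 4 lists called with the preset correlation held 0 called genes and had adjusted p from 0.23 to 0.87 with an estimated correlation. Endothelial markers, the strongest of them, had a median of -0.15 and adjusted p = 0.23 with an estimated correlation.

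Across vehicle and the 3 doses on day 11, 1155 genes had a called slope on the rank of the amiodarone dose, 693 upward and 462 downward. The slope of Cyp4a14 was 1.78 ± 0.24 (adjusted p = 1.6e-08) and was carried by the high dose, with group means of 7.41, 6.46, 8.66 and 12.63 from vehicle to high dose, and that of Cyp4a31 was 1.48 ± 0.09. Slopes were -0.84 ± 0.20 for Ugt2b38, a male-predominant glucuronosyltransferase gene, -0.77 ± 0.13 for Tff3 and -0.74 ± 0.12 for Serpina12. A slope does not show a change at each dose. The effect of the high dose differed between days 4 and 1 for 89 genes, 55 upward and 34 downward, and between days 11 and 1 for 18 genes, 15 upward and 3 downward. Mogat1 was larger on the later days, by 1.94 ± 0.23 on day 4 and by 2.21 ± 0.21 on day 11, and Lpl was larger by 2.02 ± 0.30 on day 11. Cyp2b10 and Cyp4a14 had differences of 0.37 ± 0.50 and 0.93 ± 1.12 between days 11 and 1, which were not called.

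The count of 89 was 31 with only the arrays compared in the fit, 48 and 56 without day 1 amiodarone arrays 045 and 064, 50 without day 4 array 069, 45 and 53 without PBS arrays 025 and 050, and 41 without PBS array 041. The count of 18 was 11 and 9 without arrays 045 and 064, 8, 29 and 10 without day 11 amiodarone arrays 031, 033 and 062, and 9, 10 and 10 without PBS arrays 020, 073 and 090. It was 14 after quantile normalizing again, 10 upward and 4 downward, 11 with only the arrays compared and 28 with dim genes left out.

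On day 1 high-dose valproic acid raised acute phase and chaperone genes and lowered genes of bile acid synthesis and transport and of fatty acid synthesis. Lcn2 (Entrez Gene 16819), which encodes the acute phase protein lipocalin 2, stood at 12.38 ± 0.25 (SD, n = 4) against 5.19 ± 1.38 (SD, n = 4) with PBS, a 146-fold rise (7.19 ± 1.07, adjusted p = 1.4e-07). Prtn3, which encodes proteinase 3, rose by 5.74 ± 0.58 on the log2 scale, the metallothionein gene Mt2 53.3-fold (5.74 ± 0.88) and the serum amyloid gene Saa2 43.8-fold (5.45 ± 0.97). Rgs16, which encodes a regulator of G protein signalling, fell by 3.76 ± 0.46 (adjusted p = 7.5e-10), Clec2h by 3.59 ± 0.42 and Nrep by 3.29 ± 0.51. All 20 acute phase genes rose, also all 20 adjusted over the list alone (median 1.49, list adjusted p = 1.4e-33). Of 9 neutrophil markers 2 rose, S100a8 (2.14) and S100a9 (2.42), also 2 adjusted over the list alone (median 0.02, list adjusted p = 0.41).

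Of 19 endoplasmic reticulum chaperone genes 17 rose and 1 fell, the same counts adjusted over the list alone (median 0.79, list adjusted p = 1.8e-20), with Creld2 (2.10 ± 0.32) and Sdf2l1 (2.01 ± 0.31). Of 16 cholesterol synthesis genes 12 rose and 1 fell, the same counts adjusted over the list alone (median 0.81), with the squalene epoxidase gene Sqle (Entrez Gene 20775, 1.67 ± 0.27, adjusted p = 9.1e-07) and Mvd (1.66 ± 0.34), but the list had adjusted p = 0.17 with an estimated correlation. Of 23 genes of bile acid synthesis and transport 14 fell, or 15 adjusted over the list alone (median -0.50, list adjusted p = 3.4e-12), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis, to 0.26 of vehicle (-1.95 ± 0.47, adjusted p = 0.0011), and the transporter gene Slco1a4 (-1.81 ± 0.28). Of 22 fatty acid and triglyceride synthesis genes 12 fell, or 14 adjusted over the list alone (median -0.60), with the lipogenic regulator gene Thrsp (-1.65 ± 0.30) and the elongase gene Elovl3 (-1.57 ± 0.40). Of 23 nuclear genes of oxidative phosphorylation 12 fell, or 16 adjusted over the list alone (median -0.18), with Sdhd (-0.50 ± 0.06).

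Of 14 genes of gluconeogenesis and insulin response 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (median -0.17), with the liver glycogen synthase gene Gys2 (-1.67 ± 0.13, adjusted p = 1.6e-17) and Slc2a2 (-1.12 ± 0.10). Of 18 coenzyme A and carnitine genes 6 fell, or 9 adjusted over the list alone (median -0.18), with Acsm5 (-0.95 ± 0.10). Of 10 periportal markers 4 fell and 1 rose, or 6 and 1 adjusted over the list alone, with Etnppl (-2.37 ± 0.20) and Cyp2f2 (-0.65 ± 0.08), at a median of -0.19, or -0.11 without PBS array 025. Other genes that fell included the clock output gene Dbp (-1.53 ± 0.16), the cyclin gene Ccnd1 (-1.97 ± 0.25), Keg1 (-2.02 ± 0.26) and Cyp2c55 (-2.49 ± 0.24). Cyp3a11 fell by 0.32 ± 0.05 and Cpt1a, which encodes the carnitine palmitoyltransferase of mitochondrial fatty acid entry, by 0.48 ± 0.12, while Cyp4a14 rose by 3.49 ± 0.83 (adjusted p = 0.0011).

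In all, 1316 genes were called higher and 1273 lower on day 1 (1288 and 1304 after quantile normalizing again), 262 by more than 2-fold. Of 18 lists called with the preset correlation, 8 also passed with an estimated correlation, and those not yet named, among them cell cycle, lipid droplet and male-biased genes, had adjusted p from 0.081 to 0.27 with an estimated correlation. The number of genes was 1448 with only the arrays compared in the fit.

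By day 4 acute phase genes were still higher than with PBS, and so were markers of liver macrophages and endothelium. Lcn2 rose 27.6-fold (4.79 ± 1.07, adjusted p = 0.0034), Cyp4a14 29.4-fold (4.88 ± 0.83, adjusted p = 5.2e-05), Mt2 by 3.58 ± 0.88 and Cyp2b10 by 3.30 ± 0.37 (adjusted p = 6.3e-10). Of 20 acute phase genes 9 rose, or 17 adjusted over the list alone (median 0.61, adjusted p = 0.046 with an estimated correlation). Of 16 Kupffer cell and macrophage markers 8 rose, or 13 adjusted over the list alone (median 0.69, adjusted p = 0.046 with an estimated correlation), with the haemoglobin scavenger receptor gene Cd163 (0.90 ± 0.19, adjusted p = 0.0019). Of 14 endothelial markers 2 rose, or 10 adjusted over the list alone (median 0.29), with Clec4g (0.46 ± 0.08). Of 24 genes of the ATF4 stress response 2 rose, also 2 adjusted over the list alone (median 0.12, adjusted p = 0.046 with an estimated correlation). Those were Chac1 (1.45 ± 0.39), not called without valproic acid arrays 004, 068 and 092 or PBS arrays 041 and 044 (1.34 to 1.41), and Slc3a2 (0.40 ± 0.11), not called without arrays 004, 068 and 092 or PBS array 087 (0.34 to 0.40).

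On day 4 Serpina12 fell by 2.70 ± 0.44, Rgs16 by 2.46 ± 0.46, Thrsp by 1.53 ± 0.30, the pyruvate kinase gene Pklr by 1.32 ± 0.22 and the haem synthesis gene Alas2 of erythroid cells by 0.91 ± 0.20. The erythrocyte list itself (1 of 4 lower, also 1 adjusted over the list alone, median -0.15, and -0.23 with dim genes left out) had adjusted p = 0.13 with an estimated correlation and was not called without valproic acid arrays 004, 008 and 068 or PBS array 087 (median -0.11 to -0.16). Male-biased genes (3 of 14 lower, or 7 adjusted over the list alone, median -0.63) had adjusted p = 0.11 with an estimated correlation, and PPARA targets (7 of 23 higher and 1 lower, or 9 and 1 adjusted over the list alone, median 0.30, and 0.19 without PBS array 040) had adjusted p = 0.075 with an estimated correlation. In all 389 genes were called, 217 higher and 172 lower, and 4 of 21 lists called with the preset correlation passed with an estimated one. The count was 219 and 258 without valproic acid arrays 004 and 068, and 251 with only the arrays compared.

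After 11 days high-dose valproic acid had raised CAR and PXR genes, amino acid catabolism and fatty acid oxidation, and had lowered male-biased genes. Cyp2b10 stood at 6.69 ± 0.49 (SD, n = 5) against 2.76 ± 0.16 (SD, n = 5), a rise of at least 3.93 ± 0.33 (adjusted p = 3.5e-15), since the vehicle level lies below the array median. Cyp4a14 rose 29.5-fold (4.88 ± 0.75, adjusted p = 1.4e-06), and Cyp2b9 (Entrez Gene 13094), a cytochrome P450 gene of female mouse liver, rose by 4.48 ± 0.54 (adjusted p = 3e-09). Hsd3b5 (Entrez Gene 15496), a steroid dehydrogenase gene of male mouse liver, stood at 7.55 ± 2.09 against 11.14 ± 0.07 and fell by 3.58 ± 0.59 (adjusted p = 6.7e-06). Serpina4-ps1, a serpin pseudogene (-5.06 ± 0.68), and Ugt2b38 (-4.69 ± 0.64) fell as well.

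Of 23 CAR and PXR genes 15 rose, also 15 adjusted over the list alone (median 0.40, list adjusted p = 3.2e-15), with Cyp2c38 (1.54 ± 0.24). Of 18 genes of the urea cycle and amino acid catabolism 11 rose, or 12 adjusted over the list alone (median 0.36, list adjusted p = 2e-14), with the transaminase gene Got1 (1.18 ± 0.24), the proline dehydrogenase gene Prodh (0.85 ± 0.16) and Cth, an enzyme of cysteine synthesis (0.66 ± 0.10). Of 14 male-biased genes 10 fell, or 12 adjusted over the list alone (median -0.72, list adjusted p = 5.4e-18), with the complement gene C6 (-1.96 ± 0.21) and the oxysterol hydroxylase gene Cyp7b1 (-1.78 ± 0.34). Of 14 female-biased genes 6 rose, or 8 adjusted over the list alone (median 0.39, list adjusted p = 1.7e-07). The median was 1.43 with dim genes left out. Cyp17a1 (2.33 ± 0.46) and the PPARA target Acot3 (2.63 ± 0.59) rose. Of the 14, 5 are also in other lists (Cyp2b9 in CAR and PXR). Of 18 mitochondrial oxidation genes 10 rose, or 14 adjusted over the list alone (median 0.29), with the acyl-CoA dehydrogenase genes Acadl (0.56 ± 0.07) and Acadm (0.45 ± 0.08). Of 23 PPARA targets 11 rose and 1 fell, or 14 and 2 adjusted over the list alone (median 0.34), with Ehhadh (2.04 ± 0.16), Cyp4a31 (2.47 ± 0.29) and Cyp4a10 (2.42 ± 0.33).

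Of 19 endoplasmic reticulum chaperone genes 8 fell and 1 rose, or 12 and 1 adjusted over the list alone (median -0.44, list adjusted p = 1.9e-10), with Creld2 (-1.07 ± 0.29) and the calreticulin gene Calr (-0.62 ± 0.12). Of 12 mitochondrial chaperones and proteases 3 rose, or 4 adjusted over the list alone (median 0.14, or 0.09 after quantile normalizing again), with Clpx (1.17 ± 0.17), and of 21 mitochondrial ribosome genes 6 rose, or 7 adjusted over the list alone (median 0.13), with Mrps9 (0.45 ± 0.08). Further genes that rose were Gstt3 (2.22 ± 0.25), Cd36 (1.94 ± 0.22) and Mfsd2a, which encodes a transporter of lysophospholipids (1.93 ± 0.54). Further genes that fell were Serpina12 (-3.36 ± 0.39), Tff3 (-2.91 ± 0.42), Adgrf1 (-1.96 ± 0.31) and Osgin1 (-1.74 ± 0.25). Plin2 had a value of -0.14 ± 0.13 (adjusted p = 0.64).

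High-dose valproic acid on day 11 thus had 970 genes called higher and 517 lower, 88 by more than 2-fold, and 750 higher and 710 lower after quantile normalizing again. The 9 lists above were those that passed with both correlations, of 15 called with the preset one. Cholesterol synthesis (6 of 16 higher, or 12 adjusted over the list alone, median 0.51, and 0.33 without valproic acid array 006) had adjusted p = 0.18 with an estimated correlation. Glucocorticoid response genes (2 of 15 higher, also 2 adjusted over the list alone, median 0.23) had adjusted p = 0.18 with an estimated correlation, and were not called without array 049 (median 0.16) or with dim genes left out. Their median was 0.34 without PBS array 032.

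Valproic acid at 250 mg/kg on day 11 changed 701 genes, 455 higher and 246 lower, or 374 and 347 of 721 after quantile normalizing again. Cyp4a14 rose by 4.65 ± 0.75 (adjusted p = 1.4e-05), Cyp2b9 by 4.17 ± 0.54 and Cyp2b10 by 2.52 ± 0.33 (adjusted p = 2.1e-07), while Ugt2b38 fell by 3.38 ± 0.64 and Serpina12 by 2.60 ± 0.39. Of 14 male-biased genes 13 fell, also 13 adjusted over the list alone, with a median of -1.08 (adjusted p = 0.005 with an estimated correlation), and -0.59 without valproic acid array 067. Of 23 CAR and PXR genes 11 rose, or 15 higher and 2 lower adjusted over the list alone (median 0.26, adjusted p = 0.005 with an estimated correlation). Female-biased genes (5 of 14 higher, or 6 adjusted over the list alone, median 0.23) had adjusted p = 0.051 with an estimated correlation, and a median of 0.12 without array 067 and 1.11 with dim genes left out. The other 8 lists called with the preset correlation had adjusted p from 0.059 to 0.33 with an estimated correlation. The number of genes was 411 without array 067 and 214 with only the arrays compared in the fit.

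Valproic acid at 125 mg/kg changed 9 genes, 7 higher and 2 lower, or 6 and 4 of 10 after quantile normalizing again. The kinase gene Nuak2 fell by 0.87 ± 0.16 (adjusted p = 0.0052) and Adssl1, an enzyme gene of purine synthesis, rose by 0.72 ± 0.14. Without array 026 limma called 0 genes, and Nuak2 then had a value of -0.78 (adjusted p = 0.0574). The count was 4, 16, 1 and 19 without arrays 019, 046, 056 and 071, and 4, 4 and 3 without PBS arrays 002, 073 and 090, and 5 with only the arrays compared, not Nuak2 or Adssl1 (adjusted p = 0.0823 each). Cyp4a14 had a value of 3.07 ± 0.75 (adjusted p = 0.088), but was called with only the arrays compared (adjusted p = 0.0152), and its 5 treated arrays (9.70 to 11.30) lay above the 5 PBS arrays (6.52 to 8.65). The 8 lists called with the preset correlation had adjusted p from 0.31 to 0.82 with an estimated correlation, and 5 were called without array 071, PBS array 020 or PBS array 032.

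Across the doses of valproic acid on day 11, 1636 genes had a called slope on the dose rank, 1040 upward and 596 downward, or 837 and 789 after quantile normalizing again. The slopes were 1.76 ± 0.17 for Cyp2b9 (adjusted p = 8.7e-13), 1.62 ± 0.24 for Cyp4a14 and 1.39 ± 0.11 for Cyp2b10. They were -1.86 ± 0.21 for Serpina4-ps1, -1.64 ± 0.20 for Ugt2b38 and -1.33 ± 0.19 for Hsd3b5.

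The effect of high-dose valproic acid changed with time in 1000 genes between days 4 and 1 (500 upward, 500 downward) and in 2023 between days 11 and 1 (1147 upward, 876 downward). Relative to day 1, Cyp2b10 was higher by 3.62 ± 0.53 on day 4 and by 4.25 ± 0.50 on day 11, and Sqle was lower by 2.23 ± 0.38 and 1.57 ± 0.36. The cytokine signalling gene Socs2 (3.35 ± 0.81) and Acot1 (2.61 ± 0.48) were higher on day 4, and Crybb3 (-3.84 ± 0.33) and the chemokine gene Cxcl1 (-3.49 ± 0.78) were lower. On day 11 Rgs16 (4.71 ± 0.62), the hepcidin gene Hamp2 (4.54 ± 0.61) and Cyp2b9 (4.39 ± 0.81) were higher relative to day 1, and Saa2 (-5.97 ± 1.30), Prtn3 (-5.53 ± 0.77) and Lcn2 (-5.21 ± 1.43) were lower. Cyp7a1 was higher by 2.01 ± 0.62 (adjusted p = 0.021) on day 11, but was not called without array 080 (1.73) or array 006 (1.81). The number of genes between days 4 and 1 was 488 with only the arrays compared.

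**Figure D2:**
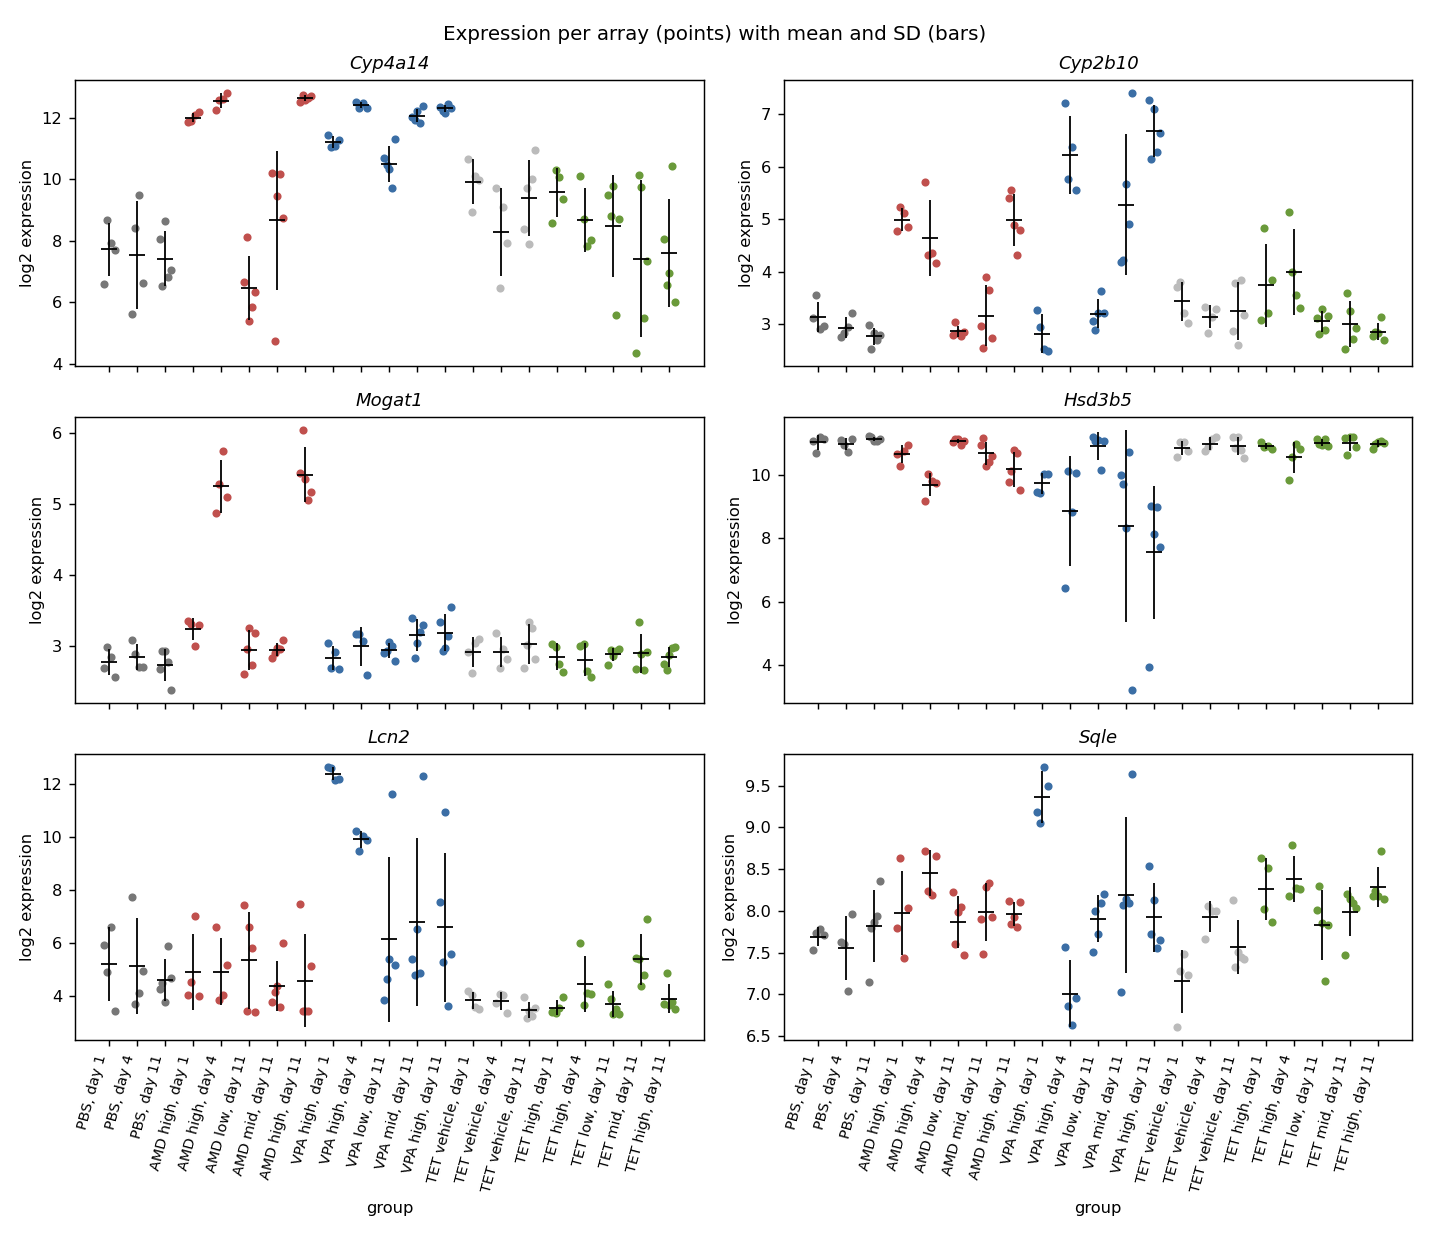
Expression (log2) of 6 genes on each array (points), with the group mean and SD (bars), in the 21 groups. Cyp4a14 lies between 12.50 and 12.73 on the 5 arrays of high-dose amiodarone on day 11 and between 6.52 and 8.65 on those of PBS, and Mogat1 lies between 5.07 and 6.05 against 2.38 and 2.93.

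Tetracycline at the high dose on day 1 changed 107 genes, 54 higher and 53 lower, with higher cholesterol synthesis genes among them. Adcy6 (Entrez Gene 11512), which encodes an adenylate cyclase, fell by 0.96 ± 0.18 (adjusted p = 0.0027). The mevalonate pathway gene Mvd rose by 1.52 ± 0.34 (adjusted p = 0.014) and Sqle by 1.11 ± 0.27 (adjusted p = 0.028). Of 16 cholesterol synthesis genes 4 rose, or 11 adjusted over the list alone (median 0.47, list adjusted p = 4.5e-11), with adjusted p = 0.28 with an estimated correlation. PPARA targets (0 of 23 called, or 7 lower adjusted over the list alone, median -0.32, and -0.20 without vehicle array 038) had adjusted p = 0.28 with an estimated correlation, and 0 of the 8 lists called with the preset correlation passed with an estimated one.

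These calls rested on single arrays. The count was 52, 182, 26 and 31 without tetracycline arrays 011, 057, 084 and 096, and 49, 52 and 18 without vehicle arrays 027, 034 and 077. Mvd was not called without arrays 011 (1.39), 084 (1.43), 027 (1.43) or 077 (1.48), and Sqle was not called without 011 (0.98), 084 (1.02), 027 (0.93), 034 (1.15) or 077 (1.13). With blocks of sample numbers neither was called (1.38 for Mvd and 0.92 for Sqle), nor was Sqle with only the arrays compared (adjusted p = 0.0659). The count was 12 with only the arrays compared, 16 with blocks of sample numbers, 218 with dim genes left out and 247 with array weights, and centring the arrays gave 40 genes higher and 60 lower.

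On day 4 limma called 0 genes for high-dose tetracycline at an adjusted p under 0.05, the smallest being 0.0549, and 1386 at an unadjusted p under 0.05. The count was 2 under 3 other settings (centred arrays, quantile normalizing again, and a variance trend), 5 with dim genes left out and 25 with array weights, and 3, 2 and 3 without arrays 054, 060 and vehicle array 088. Cholesterol synthesis genes (0 of 16 called, or 8 higher adjusted over the list alone, median 0.38) had adjusted p = 0.35 with an estimated correlation, and urea cycle and amino acid genes (0 of 18 called, or 4 higher adjusted over the list alone, median 0.16) had adjusted p = 0.17 with an estimated correlation. Of 9 lists called with the preset correlation, 0 passed with an estimated one, and 5 were called without array 007.

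On day 11 limma called 0 genes for the high dose and 0 for the low dose of tetracycline, with 888 and 1074 genes at an unadjusted p under 0.05, and 4 for the mid dose. Cholesterol synthesis genes at the high dose (0 of 16 called, or 7 higher adjusted over the list alone, median 0.40) had adjusted p = 0.38 with an estimated correlation, and NRF2 genes (0 of 21 called, or 3 lower adjusted over the list alone, median -0.15) had adjusted p = 0.057 with an estimated correlation. At the high dose Cyp4a14 had a value of -1.79 ± 0.75, Plin2 -0.10 ± 0.13, Sqle 0.72 ± 0.24 and Fasn, the fatty acid synthase gene, -0.04 ± 0.28, and none of these was called. At the mid dose the kinase gene Sgk2 fell by 0.74 ± 0.14, Sertad2 by 0.55 ± 0.10 and Crtc3 by 0.48 ± 0.09, and Rwdd4a rose by 0.36 ± 0.08. None of these was called without array 089 or vehicle array 022 (0 genes), where Sgk2 had a value of -0.71 in both cases, or with only the arrays compared (adjusted p = 0.064 to 0.157), nor was Rwdd4a after quantile normalizing again (0.34) or with a linear sample number (0.35). The count was 10 and 17 without arrays 047 and 052, 2 and 2 without vehicle arrays 042 and 076, and 11, 19 and 20 with blocks, with dim genes left out and with array weights, and at the low dose it was 2 without array 018.

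Of the lists called with the preset correlation at the high, mid and low dose of tetracycline on day 11 (10, 11 and 8), 0 passed with an estimated one. At the high dose 4 were called without array 094 and 6 without vehicle array 076. At the mid dose 5 and 4 were called without arrays 010 and 089, and 7, 6 and 4 without vehicle arrays 022, 043 and 076. At the low dose 4, 4 and 5 were called without arrays 018, 030 and 036, and 3 without vehicle array 076. The dose trend and both differences between days gave 0 genes in limma, with 884, 1255 and 935 at an unadjusted p under 0.05, and 1 gene between days 4 and 1 without array 060 or with only the arrays compared.

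**Figure D3:**
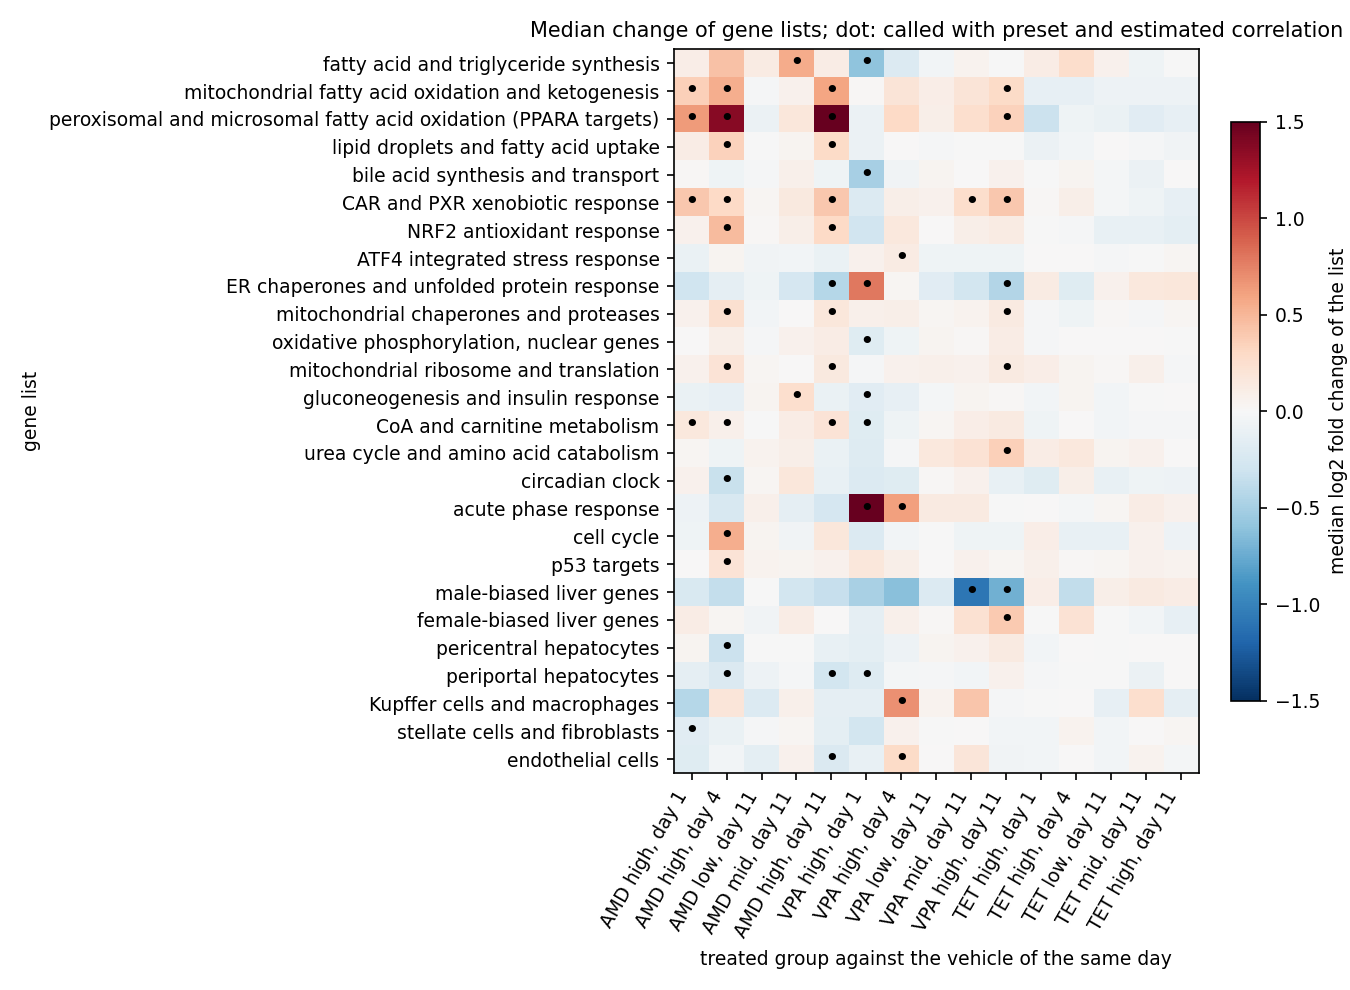
Median log2 fold change of 26 gene lists (vertical axis) in the 15 treated groups against the vehicle of the same day (horizontal axis), with a dot where the list was called with both the preset and the estimated correlation. The 54 dots lie in the columns of amiodarone and valproic acid, and the largest median is 1.49.

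The differences between compounds were tested directly on day 11 at the high dose, where the doses in mg/kg differ between compounds. Amiodarone had higher lipid storage and PPARA target genes than valproic acid, and lower Cyp2b genes and amino acid catabolism. Of 16464 genes 1327 differed, 565 higher with amiodarone and 762 lower, or 646 and 631 after quantile normalizing again. Mogat1 was higher by 2.23 ± 0.14 (adjusted p = 1.5e-21), Cyp4a31 by 2.41 ± 0.29 and Plin2 by 1.02 ± 0.13 (adjusted p = 1.9e-08). Cyp2b9 was lower by 3.95 ± 0.54, Mt2 by 3.72 ± 0.79 and Cyp2b10 by 1.70 ± 0.33 (adjusted p = 0.00015). PPARA targets were higher (15 of 23, or 19 adjusted over the list alone, median 0.76), as were lipid droplet genes (13 of 23 higher and 1 lower, or 14 and 2 adjusted over the list alone, median 0.33, or 0.50 with dim genes left out). Urea cycle and amino acid genes were lower (13 of 18, or 16 adjusted over the list alone, median -0.51), with Got1 (-1.51 ± 0.24). Pericentral markers (5 of 15, or 7 adjusted over the list alone, median -0.41) and periportal markers (5 of 10, or 7 adjusted over the list alone, median -0.32) were lower, with Lect2 (-0.92 ± 0.10) and Aldh1b1 (-0.96 ± 0.17). These 5 lists passed with both correlations, of 18 called. Cyp4a14 differed by 0.33 ± 0.75, which was not called, but it was called with only the arrays compared (adjusted p = 0.0155), where the amiodarone arrays (12.50 to 12.73) lay above those of valproic acid (12.16 to 12.45). Male-biased genes (6 of 14 higher, or 10 adjusted over the list alone, median 0.74) had adjusted p = 0.07 with an estimated correlation.

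Against tetracycline, amiodarone differed in 558 genes (362 higher, 196 lower) and valproic acid in 634 (409 higher, 225 lower, or 277 and 285 after quantile normalizing again). These are differences between effects, each against its own vehicle, and not between the levels of the 2 groups. The effect of amiodarone was higher by 7.00 ± 1.05 for Cyp4a14, 2.96 ± 0.32 for Cd36 and 0.98 ± 0.19 for Plin2, and that for Slc22a7 differed by -2.88 ± 0.50. For Cyp4a14 the vehicles themselves stood at 7.41 (PBS) and 9.38, and the groups at 12.63 and 7.59. PPARA targets (18 of 23 higher, or 20 adjusted over the list alone, median 1.68), mitochondrial oxidation (14 of 18, or 16 adjusted over the list alone, median 0.63) and lipid droplet genes (9 of 23, or 13 adjusted over the list alone, median 0.32) were among the 8 of 19 called lists that passed with both correlations. NRF2, CAR and PXR, mitochondrial chaperone and coenzyme A genes were higher and endoplasmic reticulum chaperones lower among these lists.

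The effect of valproic acid against its vehicle was higher than that of tetracycline by 6.67 ± 1.05 for Cyp4a14, 4.82 ± 0.77 for Cyp2b9 and 4.32 ± 0.47 for Cyp2b10 (adjusted p = 2.5e-10), and differed by -5.81 ± 0.96 for Serpina4-ps1. Male-biased genes were lower (8 of 14, or 11 adjusted over the list alone, median -0.91), with Hsd3b5 (-3.65 ± 0.83), and female-biased genes were higher (6 of 14, or 7 adjusted over the list alone, median 0.53, or 1.57 with dim genes left out). Of 15 lists called with the preset correlation 9 passed with an estimated one. Of these, mitochondrial chaperones (2 of 12 higher, or 4 adjusted over the list alone, median 0.15) were not called with dim genes left out (adjusted p = 0.0821) or after quantile normalizing again (adjusted p = 0.0968), and had a median of 0.08 without tetracycline array 005.

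At the high dose amiodarone and valproic acid both changed 444 genes on day 11, 288 higher, 142 lower and 14 in opposite directions. Unrelated lists of these sizes would give 41.1, 14.5 and 49.2. Across genes their log2 fold changes correlated at r = 0.554, and genes are not independent replicates. Both compounds share the PBS arrays, which alone gave a correlation of 0.5 in simulated groups. No gene changed there, so the 0 genes called in both tell nothing about the 444. With the PBS arrays split between the compounds, each had fewer. Over 10 splits 186.2 genes were shared on average (129.6 higher, 48.4 lower, 8.2 opposite) and the correlation was 0.375. On day 4 both changed 103 genes (53 higher, 45 lower, 5 opposite), and 36.8 with split PBS arrays. On day 1 both changed 59 genes, 35 of them opposite, with a correlation of 0.128. With split PBS arrays these were 32.3, 20.8 and -0.033. Valproic acid and tetracycline, which share no vehicle, both changed 56 genes on day 1, 19 higher, 30 lower and 7 opposite, against 4.32, 4.10 and 8.41 in unrelated lists.

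The vehicles themselves were compared because the effects of tetracycline rest on another baseline than those of the other compounds. The tetracycline vehicle differed from PBS in 15 genes on day 1 (9 higher, 6 lower) and 2 on day 4, and in 0 on day 11 by limma, with 1407 at an unadjusted p under 0.05. On day 1 Tff3 was lower by 2.24 ± 0.47 and the retinol saturase gene Retsat higher by 0.77 ± 0.15, and on day 4 Iars, which encodes an isoleucine tRNA synthetase, was higher by 0.65 ± 0.13 and Plpp3 lower by 0.56 ± 0.11. On day 1 the count was 36, 7 and 5 without PBS arrays 025, 050 and 082, and 0, 2, 0 and 0 without tetracycline vehicle arrays 027, 034, 038 and 077. It was 0 with blocks of sample numbers, where Tff3 and Retsat had adjusted p = 0.0854 and 0.0656, 0 with only the arrays compared, 30 with array weights and 41 with dim genes left out. On day 4 the count was 0 without any 1 of PBS arrays 040, 041, 044 and 087 or vehicle arrays 075, 085 and 088, and 21 without vehicle array 035. It was also 0 with blocks, with centred arrays and with a linear term in the sample number, 9 with dim genes left out and 35 with array weights. On day 11 it was 5 without PBS array 073, and 8 and 3 without vehicle arrays 016 and 042.

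Of the genes followed in all comparisons whatever their values, Cpt1a, Fasn, Cidec, Mttp and Cyp7a1 had no call against vehicle at the high dose on day 11 for any compound with all arrays in the fit. Their values with amiodarone were 0.09 ± 0.11, 0.29 ± 0.28, 0.24 ± 0.11, 0.15 ± 0.07 and -0.70 ± 0.42, and with valproic acid -0.04 ± 0.11, -0.08 ± 0.28, -0.09 ± 0.11, -0.16 ± 0.07 and 0.06 ± 0.42. Mttp was called with valproic acid after quantile normalizing again (-0.23, adjusted p = 0.0208). Cidec was called between amiodarone and valproic acid (0.33 ± 0.11, adjusted p = 0.048), but was not called without amiodarone arrays 012 (0.35), 031 (0.26), 033 (0.35) or 062 (0.30), without valproic acid arrays 006 (0.33), 028 (0.32), 078 (0.28) or 081 (0.35), or with only the arrays compared, array weights, quantile normalizing again or blocks. Both group means of Cidec, 2.91 and 2.58, lie below the array median, so no size of that difference can be given. Fgf21, a liver hormone gene, was lower with valproic acid on day 11 (-0.91 ± 0.27, adjusted p = 0.021), but was not called without PBS arrays 002 (-0.55) or 032 (-0.85), without valproic acid array 028 (-0.84) or with only the arrays compared.

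Some gene lists were not called for amiodarone or valproic acid at the high dose on day 11. Of 7 genes of the AHR response 1 rose with each compound, also 1 adjusted over the list alone (adjusted p = 0.98 and 0.58), and with amiodarone the list median was -0.04 while its mean was 0.10. Of 9 cholangiocyte and gallbladder markers 1 rose with each compound, also 1 adjusted over the list alone (adjusted p = 0.23 and 0.58). Of 13 lymphocyte and NK cell markers and 5 adipose markers 0 were called, and 0 adjusted over the list alone, with medians of -0.06 and 0.04 for amiodarone and -0.08 and -0.06 for valproic acid. Of 11 exocrine pancreas markers 1 fell with amiodarone and 1 rose with valproic acid (adjusted p = 0.33 and 0.4).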

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

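The tests of the arrays behind the valproic acid response of day 1 and of the sample number order behind the tetracycline response of day 1, and all counts from other splits of the arrays, were chosen only after the result was seen.

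In 18 of 252 cases for the genes followed in every group, 1 array lay far from the others of its group by a gap test, where 13 would be expected by chance. The value of the test is the gap as a share of the range. Cyp2b10 stood at 5.72 on amiodarone array 017 of day 4 against 4.17 to 4.35 on the others (0.881), and at 3.04 on low-dose amiodarone array 059 (0.718). Cyp3a11 stood at 12.54 on valproic acid array 079 of day 1 (0.912), and Cpt1a at 8.94 on valproic acid array 049 of day 11 (0.823). Cyp4a14 stood at 4.74 on mid-dose amiodarone array 065 against 8.75 to 10.18 (0.736), and at 5.59 on low-dose tetracycline array 036 against 8.70 to 9.77 (0.745). Fgf21 stood at 5.45 on PBS array 025 of day 1 against 2.57 to 2.71 (0.951), at 4.42 on high-dose tetracycline array 048 of day 11 (0.869) and at 2.26 on array 054 of day 4 (0.857).

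Sqle was set apart on high-dose tetracycline array 048 of day 11 (8.72, 0.835), array 021 of day 4 (8.78, 0.839) and mid-dose array 010 (7.47, 0.77), and on vehicle arrays 016 of day 11 (8.13, 0.776) and 035 of day 4 (7.66, 0.86). Cyp7a1 was set apart on array 048 (7.50, 0.719), Plin2 on mid-dose amiodarone array 066 (10.60, 0.776) and tetracycline array 084 of day 1 (10.80, 0.935), and Cidec on valproic acid array 004 of day 4 (2.23, 0.891).

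The effect of the high dose differed between days for 89 genes (days 4 and 1) and 18 genes (days 11 and 1) of amiodarone, and for 1000 and 2023 genes of valproic acid. Among the followed genes these were, for valproic acid between days 4 and 1, Cyp2b10 (3.62 ± 0.53), Cyp3a11 (0.37 ± 0.07) and Sqle (-2.23 ± 0.38). Between days 11 and 1 they were Cyp2b10 (4.25 ± 0.50), Cyp3a11 (0.29 ± 0.07), Sqle (-1.57 ± 0.36) and Cyp7a1 (2.01 ± 0.62).

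Valproic acid on day 1 differed from days 4 and 11 by a large acute phase response. Aberrant treated arrays are excluded as the cause, since the lowest of the 4 treated arrays lay 1.41 above the highest PBS array in the median of the acute phase list. PBS arrays out of line are excluded too, since the change against the other vehicle of day 1 was 1.11 times that against PBS. Neutrophils in the tissue remain possible, at a median of 0.02 over 9 markers. That value met the bound set beforehand for excluding them, but after it was seen it was not taken as decisive, because the markers spread by an SD of 1.01 and S100a8 and S100a9 rose.

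High-dose tetracycline had 107 genes called on day 1 and 0 on days 4 and 11, but 0 were called between days. Day 1 vehicle arrays out of line could not be told from an effect of the compound, since the median change of the 107 genes against PBS was 0.552 of that against their own vehicle, with 104 of the same sign. Blocks kept 0.932 of the change, in genes chosen without them. Only 16 genes were called with blocks, so sample number order is left open. The 107 genes had medians of 0.14 on day 4 and 0.13 on day 11, with 88 and 96 of the same sign.

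Within groups 1401 genes drifted with the sample number, and chance is excluded, since only 1 of 100 exchanges of the numbers within groups, the real order, gave as many genes, and the highest other gave 2. Dissection order through the day may be a cause and could not be told, since 5.56% of the 18 clock genes drifted (exact 95% interval 0.141 to 27.3%) against 8.51% of other genes. Array brightness (r = -0.029, permutation p = 0.78) could not be told either, since the deposited values were already scaled to a common distribution. Both values met the bounds set beforehand for excluding these causes, and were held back for these reasons after they were seen.

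The arrays of each comparison were also split in every other way, or in 100 ways where there are more, to ask whether groups drawn at random give as many genes. Chance is taken as excluded at a share under 0.05, but 48 counts were tested with no correction and the smallest share of 35 splits is 0.0286, so chance is excluded firmly for none of them. The real grouping was the only split as large for amiodarone on day 1 (131 genes, highest other 22), day 4 (1022, 176) and day 11 at the high dose (1161, 416), and for its dose trend (1155, 378). The same held for valproic acid on day 1 (2589, 1279), day 4 (389, 33) and day 11 at the mid dose (701, 190). It also held for its high dose on day 11 (1487, 391) and its dose trend (1636, 253). It held for tetracycline on day 1 (107, 2), amiodarone against valproic acid (1327, 384) and tetracycline (558, 442), and valproic acid against tetracycline (634, 568). The vehicles on day 1 (15, 6) and day 4 (2, 0) also had no other split as large, but both counts were 0 with blocks, so chance is left open. Each was 1 of 35 or 100 splits.

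The share was also under 0.05 where 2 of 100 splits were as large, for mid-dose amiodarone (53, highest other 85), low-dose valproic acid (9, 13) and amiodarone between days 4 and 1 (89, 143), and where 3 of 100 were, for mid-dose tetracycline (4, 7). Chance cannot be excluded where 5 of 100 splits were as large, for amiodarone between days 11 and 1 (18, 141) and valproic acid between days 4 and 1 (1000, 1831). For differences between days, and for amiodarone or valproic acid against tetracycline, treated arrays were exchanged among treated groups and vehicle arrays among vehicles. A split can then keep the treated days or compounds apart while it mixes the vehicles, and so carry their difference. The splits therefore cannot decide on chance for any of these differences. No structure of the samples can be read from 141 against 18. Counts of 0 were reached by all splits, 100 of 100 for low-dose amiodarone (highest 8), tetracycline at the low (3) and high dose (2), its dose trend (87), days 11 and 1 (6), days 4 and 1 (31) and the vehicles on day 11 (15), and 35 of 35 for tetracycline on day 4 (1).

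For the number of lists, the share was under 0.05, with the same limit, for amiodarone on day 4 (23 lists, 1 of 35 splits, highest other 21) and at the mid dose (15, 1 of 100, 13), valproic acid on day 4 (21, 1 of 35, 14), mid-dose tetracycline (11, 1 of 100, 9, with 0 called at an estimated correlation) and amiodarone against tetracycline (19, 2 of 100, 21). Chance cannot be excluded for amiodarone on day 1 (16, 7 of 35, 18), at the low dose (4, 27 of 100, 9) and the high dose of day 11 (23, 6 of 100, 27), or for valproic acid on day 1 (18, 5 of 35, 21), at the low (8, 12 of 100, 11), mid (11, 24 of 100, 14) and high dose (15, 6 of 100, 17). The same holds for tetracycline on day 1 (8, 5 of 35, 11), day 4 (9, 5 of 35, 11), at the low (8, 6 of 100, 10) and high dose (10, 11 of 100, 14), for amiodarone against valproic acid (18, 11 of 100, 21) and for valproic acid against tetracycline (15, 7 of 100, 17).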

How the results depend on the processing

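The linear term in the sample number was chosen only after the result was seen, and all other alternatives were chosen before. No paired analysis was possible because the sample numbers are not shared between groups. A mean over the probe sets of a gene was not run, because each gene has 1 probe set.

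The calls for amiodarone and valproic acid at the high dose on day 11, for amiodarone on day 4, for the dose trends of both and for the differences between compounds moved by less than 1.5-fold under every alternative. Leaving out 1 array at a time gave 905 to 1094 genes for amiodarone on day 11 (1161 with all arrays), 733 to 894 on day 4 (1022) and 916 to 1180 for its dose trend (1155). For valproic acid it gave 1143 to 1444 on day 11 (1487), 2202 to 2567 on day 1 (2589), 1338 to 1714 for the dose trend (1636), 769 to 1109 between days 4 and 1 (1000) and 1762 to 2058 between days 11 and 1 (2023). It gave 1047 to 1261 genes for amiodarone against valproic acid (1327), 433 to 572 against tetracycline (558), and 464 to 718 for valproic acid against tetracycline (634).

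Smaller counts moved more with single arrays. They ran from 80 to 133 for amiodarone on day 1 (131), 0 to 140 at the mid dose (53), 0 to 1 at the low dose (0), 41 to 103 between days 4 and 1 (89) and 8 to 29 between days 11 and 1 (18). For valproic acid they ran from 219 to 382 on day 4 (389), 411 to 704 at the mid dose (701) and 0 to 19 at the low dose (9). For tetracycline they ran from 18 to 182 on day 1 (107), 0 to 3 on day 4 (0), 0 to 2 at the low dose (0), 0 to 17 at the mid dose (4) and 0 to 1 between days 4 and 1 (0). The vehicles differed in 0 to 36 genes on day 1 (15), 0 to 21 on day 4 (2) and 0 to 8 on day 11 (0). The high-dose tetracycline count of day 11, its dose trend and its days 11 and 1 stayed at 0. Fewer arrays give fewer calls by construction, and for the counts that rose the cause was not tested.

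A fit of only the arrays compared has fewer degrees of freedom and gave fewer calls. The counts were 1448 for valproic acid on day 1, 251 on day 4, 214 at the mid dose, 5 at the low dose and 488 between days 4 and 1. They were 32 for amiodarone on day 1, 0 at the mid dose, 31 between days 4 and 1 and 11 between days 11 and 1. They were 12 for tetracycline on day 1 and 0 for the vehicles on day 1, while tetracycline between days 4 and 1 gave 1. Of the calls of named genes 115 were lost in this fit.

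Leaving out dim genes tests fewer genes, and gave 28 genes for amiodarone between days 11 and 1, 113 at the mid dose, 218, 5 and 19 for tetracycline on day 1, on day 4 and at the mid dose, and 41 and 9 for the vehicles on days 1 and 4. Array weights gave 247, 25 and 20 for the same tetracycline comparisons, and 30 and 35 for the vehicles. Blocks of sample numbers gave 16 for tetracycline on day 1, 11 at the mid dose and 0 for the vehicles on days 1 and 4. Tetracycline on day 4 had 2 genes with centred arrays, 2 after quantile normalizing again and 2 with a variance trend. The vehicles on day 4 had 0 with centred arrays and 0 with the linear term. For the weights, blocks and scalings the cause was not tested.

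The number of lists fell most with an estimated correlation, which widens the test by construction where genes of a list vary together. For amiodarone it went from 16 to 5 on day 1, 23 to 13 on day 4, 4 to 0, 15 to 2 and 23 to 11 at the low, mid and high dose of day 11. For valproic acid it went from 18 to 8 on day 1, 21 to 4 on day 4, 8 to 0, 11 to 2 and 15 to 9 at the low, mid and high dose. For tetracycline it went from 8 to 0 on day 1, 9 to 0 on day 4, 8 to 0, 11 to 0 and 10 to 0 at the low, mid and high dose. Amiodarone against valproic acid went from 18 to 5, against tetracycline from 19 to 8, and valproic acid against tetracycline from 15 to 9.

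Other settings moved list counts only at low or mid doses. Low-dose amiodarone had 8 lists with only the arrays compared and 8 with blocks. Low-dose valproic acid had 5 with blocks, 4 with dim genes left out and 5 after quantile normalizing again. Mid-dose tetracycline had 7 with blocks and 7 with dim genes left out, and low-dose tetracycline 5 with dim genes left out. The cause was not tested. With single arrays left out, list counts ran from 10 to 18, 20 to 24, 3 to 6, 11 to 16 and 21 to 25 for amiodarone on day 1, day 4 and at the low, mid and high dose. They ran from 16 to 21, 16 to 21, 5 to 9, 11 to 16 and 14 to 15 for valproic acid, and from 6 to 9, 5 to 10, 3 to 9, 4 to 13 and 4 to 13 for tetracycline in the same order. They ran from 18 to 20 for amiodarone against valproic acid, 17 to 21 against tetracycline and 14 to 16 for valproic acid against tetracycline.

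The median of 3 lists changed sign when 1 array was left out. With single arrays left out, the acute phase response at the low dose of valproic acid ran from -0.044 (without array 056) to 0.19, the interferon response for amiodarone against valproic acid from -0.037 (without amiodarone array 062) to 0.19, and neutrophils with amiodarone on day 11 from -0.081 (without array 012) to 0.43. The cause was not tested. Signal over background limits the dim genes, and of the genes followed or named 10 fell below the median intensity.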

Other observations

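The description of genes that drift with the sample number was chosen only after the result was seen.

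The effect of high-dose valproic acid differed between days 11 and 1 for 2023 of 16464 genes. Lists were not tested between days. Relative to day 1, the effect on day 11 was lower for 19 of 20 acute phase genes (median -1.46) and for 17 of 19 endoplasmic reticulum chaperone genes (median -1.23). It was higher for 16 of 23 oxidative phosphorylation genes (median 0.25), 15 of 23 bile acid genes (0.52) and 8 of 14 female-biased genes (0.62). The same held for 13 of 18 urea cycle and amino acid genes (0.46) and 15 of 23 CAR and PXR genes (0.58, 1 lower). Some lists were mixed, like cholesterol synthesis (2 higher and 5 lower of 16, median -0.37) and ATF4 genes (3 and 8 of 24, -0.22). By day 4 the effect was already lower for 15 of 19 chaperone genes and 7 of 16 cholesterol synthesis genes, and higher for 10 of 23 bile acid genes. On day 4 it was higher for 5 of 16 liver macrophage markers (median 0.77) and 5 of 14 endothelial markers (0.43). On day 11 these medians were -0.01 and 0.14. Amiodarone, with the same PBS arrays, had day 4 medians of 0.74 and 0.11 (0 called), so valproic acid may not cause the macrophage shift. The amiodarone effect was higher on day 4 for 6 of 22 cell cycle genes (median 0.61).

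The sample numbers of the labels, from 1 to 96, went with the level of 1401 genes within the groups, 723 falling and 678 rising over the range, with a median absolute log2 change of 0.21. The largest changes were those of Plekha5 (-1.98 ± 0.18), Onecut1 (-1.75 ± 0.41) and Dnajb12 (-1.08 ± 0.10), and of Depp1 (0.76 ± 0.23), Tomm22 (0.68 ± 0.07) and Nhsl1 (0.63 ± 0.10). These genes were chosen after their values were seen.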
